A study of Mus musculus with 9 samples.

How the data were processed

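RNA-seq was measured in 9 libraries of sorted plantar interfollicular basal cells from wild-type C57BL/6 mice, 3 each from control, HFD and aged animals. Per the labels, skin was trypsinized at 37 °C, CD49f positive and CD34 negative cells were sorted, RNA with an integrity number above 7 was kept, and TruSeq stranded mRNA libraries were sequenced on a NextSeq500. The authors deposited 1 table of FPKM (fragments per kilobase of gene per M fragments), with 1 column per library and 22399 rows, nearly all protein-coding. The processing notes list cutadapt, STAR 2.6.0c, HTSeq 0.11.2, DESeq2 1.30.0 and the mm10 genome, without saying which tool made the FPKM or with which gene lengths. Whether reads were counted by strand is not stated, so genes that overlap others on the opposite strand are uncertain. The series also describes single-cell data from dermis, which were not used here.

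Low FPKM multiplied by the merged exon length fell on whole multiples of 1 step per library (97.5% to 98.2% of values up to 30 reads, tolerance 0.02). The step gives an estimated depth, in M reads, of 31.5, 23.5 and 31.3 in control replicates 1 to 3, 35.8, 27.6 and 26.4 in HFD and 33.0, 31.5 and 30.0 in aged. The 10 genes with most reads took 9.12% to 10.3% of reads per library, and mitochondrial genes 0.946% to 1.26%. Of 13 mitochondrial genes listed, 6 were under 1 FPKM everywhere and 4 were listed at 0, so these are uncertain. Spearman's rho between libraries of a group was 0.977 to 0.980 over genes. Squared differences between libraries of a group were at the median 7.55 to 18.6 times the counting noise, over genes with enough reads. For such genes, which leave out the low ones, precision was limited by the spread between libraries more than by depth. Median-ratio scaling factors were equal in all libraries, so the deposited values were already scaled in that way.

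Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided tests), for the 10367 genes with a mean of at least 1 FPKM over the 9 libraries. A single model with a mean per group used all 9 libraries (6 residual and 5.50 prior degrees of freedom). The 3 comparisons were HFD against control, aged against control and aged against HFD, and the F test asked which genes differed among the groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Spread is given as SD of FPKM over 3 libraries or as the SE of limma. Of 34 gene lists, the 25 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of 75 list results 30 were called, 0 held with the correlation estimated for each list, and 19 were called with fry, which tests whether a list's own genes move, on balance, one way. Camera with the estimated correlation is printed beside each call.

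The lists covered basal keratinocyte identity, hemidesmosome and basement membrane adhesion, spinous and granular differentiation, plantar and stress keratins, cell cycle, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, glycolysis and hypoxia, inflammation, type I interferon, MHC class II, senescence, YAP response, calcium and NFAT signalling, immediate early and heat shock genes, the clock and NRF2. Others held markers of sweat gland, hair follicle and sebaceous, melanocyte, Merkel, Langerhans and myeloid, T, fibroblast, endothelial and mural, muscle, fat, Schwann and erythroid cells, and sex-linked genes. The groups, tests, lists, rule for named genes and other settings to try were fixed before the data were examined. Named genes were, in each comparison with control, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap (5 and 5 for aged against HFD). Up to 4 members of each list with the smallest unadjusted p were added, as were up to 5 genes per direction called in both HFD and aged. Itga6, Cd34, Krt5, Krt14, Krt15, Trp63, Krt1, Krt10, Ivl, Mki67, Piezo1 and Cdkn2a were always named. Predicted gene models were left out, and results for a few named genes are not reported here.

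The other settings were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, quantile normalization, median-ratio scaling, library weights, limma's robust setting, a replicate block, a minimum log2 fold change of 1, only the 6 libraries compared, and leaving out each library in turn. A GC correction, alone, with the replicate block or without aged replicate 3, and scaling to total FPKM were chosen after seeing the data. The GC correction subtracted, per library, a loess curve (span 0.5, degree 1) of the deviation from the gene's mean on the GC content of the longest transcript. Gene positions and sequences came from GENCODE M21 on GRCm38, which matched 22285 of the identifiers, and stretches of 50 bases shared with transcripts of other genes were counted.

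The steps were tested on simulated data with 10 draws of 200 changed genes among 10367. Limma found 9.10% of genes changed by 0.25 on the log2 scale, 78.4% at 0.5 and 99.5% at 1, with 6.9 false calls per draw. An unchanged aged group had 0 calls. With an added GC trend there were 213.9 false calls, and 7 after the correction. Data of 9 libraries in which no group differed were also simulated 100 times, to give the correlation that shared controls produce, with and without the GC correction. Other splits of the libraries were counted, all 10 for each pair of groups and 100 drawn for the 3 groups.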

Results

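The series sequenced RNA from basal keratinocytes of mouse footpad skin, the cells that sit on the basement membrane and renew the epidermis between hair follicles. Cells were released with trypsin and sorted for CD49f, the integrin alpha 6 chain that basal cells carry, and against CD34, a marker of hair follicle stem cells. The 9 libraries came from wild-type C57BL/6 animals in 3 groups of 3. Control animals ate a normal diet and were 5 months old. HFD animals ate a high-fat diet and were also 5 months old. Aged animals were 24 months old, and the labels give them no diet. The labels do not say whether the 3 samples of a group came from separate animals. Every p-value then measures the spread between these samples, which may be technical. Expression is given as the deposited FPKM, as mean ± SD over 3 libraries. Fold changes are differences of log2(FPKM + 1) ± SE from limma. Depth, estimated from the value of a single read among low genes, was 23.5 to 35.8 M reads per library with a median of 31.3 M. Between 10230 and 10414 genes reached 1 FPKM in a library.

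The libraries carried high levels of basal keratinocyte genes in all 3 groups, together with transcripts of differentiating cells. Of 44 spinous and granular genes listed, 39 reached the expression minimum, the highest at a mean of 4639 FPKM over all libraries. Krt5 and Krt14, the keratin pair of basal cells, stood at 11465 ± 1838 and 12136 ± 1784 FPKM in control. Neither passed the test in any of the 3 comparisons (lowest adjusted p = 0.165, for Krt14 in aged against HFD). Trp63, the transcription factor that maintains epidermal progenitors, was at 93.9 ± 3.87 FPKM in control, 89.5 ± 9.50 in HFD and 79.4 ± 8.38 in aged. Krt15, a keratin of basal and stem cells, had mean FPKM of 858, 695 and 813. Neither of these was called in any comparison. Itga6, which encodes the CD49f used for sorting, was at 134 ± 3.74, 164 ± 3.61 and 124 ± 8.10 FPKM. Cd34 did not exceed 0.0671 FPKM in any library. Of 10367 genes with a mean of at least 1 FPKM, 2110 differed among the groups by limma's F test. Without control replicate 2, HFD replicate 1, 2 or 3 that count was 1206, 1225, 1167 and 1320. On the first principal component, which held 31.9% of the variance, control libraries lay between -17.0 and -12.4 and HFD libraries between 8.33 and 13.0. Aged replicates 1 and 2 were at 7.61 and 7.08, and aged replicate 3 was at -0.41. The second component, with 26.5%, set aged, at 10.8 to 16.2, apart from HFD, at -13.4 to -8.67.

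**Figure D1:**
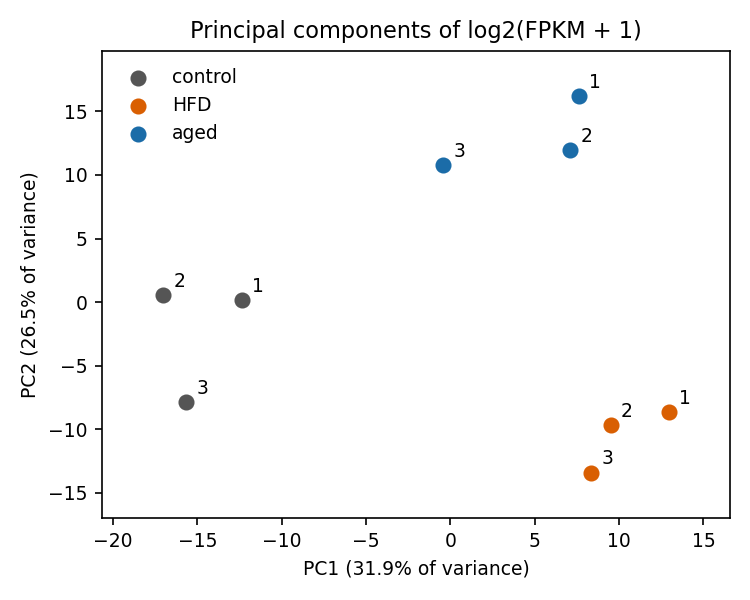
Principal components of log2(FPKM + 1), with the first component (31.9% of variance) on the horizontal axis and the second (26.5%) on the vertical axis. Each point is 1 library, coloured by group and numbered by replicate, and the 3 control libraries lie at -12.4 or lower on the first component.

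The comparison of HFD with control addressed how a high-fat diet alters basal cells at the same age. The largest rise was in Fbp2, the muscle form of a gluconeogenic fructose bisphosphatase, from 0.278 ± 0.298 to 7.50 ± 1.14 FPKM (log2 fold change 2.75 ± 0.17, adjusted p = 3.6e-05). S100a8 and S100a9, which encode the subunits of the alarmin calprotectin, rose by 2.31 ± 0.40 and 2.47 ± 0.60. Adh1, an alcohol dehydrogenase that also oxidises retinol, fell by 1.96 ± 0.19 (adjusted p = 7.8e-04), from 15.2 ± 1.09 to 3.32 ± 1.54 FPKM. Mki67 and Cenpe, genes of dividing cells, rose, and Srebf2, the regulator of cholesterol synthesis, fell. Limma called 856 genes higher and 908 lower in HFD, of which 19 and 20 changed by at least 1 on the log2 scale.

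Other large rises included Dbp, a transcription factor driven by the circadian clock (1.68 ± 0.22, adjusted p = 0.00151), and Vsnl1, a neuronal calcium sensor (1.46 ± 0.21). Ehf, an epithelial transcription factor of the ETS family, went from 2.49 ± 0.624 to 9.35 ± 1.60 FPKM (adjusted p = 0.00236). Postn, a secreted matrix protein, rose from a mean of 42.8 to 105 FPKM (1.28 ± 0.18). Gpha2, a subunit of the glycoprotein hormone thyrostimulin, rose by 1.43 ± 0.18. Ly6k, a lipid-anchored surface protein, rose by 1.60 ± 0.25, and Igfl3, an IGF-like secreted factor, by 1.31 ± 0.35. After Adh1 the largest fall was in Npas2, a clock transcription factor (-1.50 ± 0.20, adjusted p = 0.00147). The late cornified envelope genes Lce1a1 and Lce1b had -1.45 ± 0.30 and -1.20 ± 0.28. Mmp3, a matrix metalloproteinase, fell by 1.37 ± 0.24, and Fscn1, which bundles actin, by 1.21 ± 0.23. Papln, an extracellular matrix protein, and Osgin1, a gene induced by oxidative stress, had log2 fold changes of -1.20 ± 0.13 and -1.16 ± 0.17. Slc16a6, of the monocarboxylate transporter family, and Etv4, a transcription factor downstream of FGF signalling, had -1.14 ± 0.16 and -1.13 ± 0.10. The S100a9 call ended without control replicate 2 or 3 or HFD replicate 2 or 3 (adjusted p up to 0.0750), that of Igfl3 without any control library or HFD replicate 1 or 2 (0.0979), and that of Lce1b without HFD replicate 3 (0.0545). With no filter on low values their adjusted p was 0.0721, 0.0934 and 0.0539, with limma's robust setting 0.0744 for S100a9 and 0.0631 for Igfl3, and with a pseudocount of 0.1 0.0504 for S100a9.

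Of the 42 cell cycle genes tested, 22 rose and 1 fell in HFD (24 and 2 adjusted over the list alone), with a median of 0.40. For the cell cycle list camera gave adjusted p = 1.1e-07, and adjusted p = 0.576 with an estimated correlation. Mki67, the proliferation marker, went from 89.5 ± 10.1 to 155 ± 7.89 FPKM (adjusted p = 0.00159). Cenpe and Cenpf, kinetochore proteins, rose by 1.04 ± 0.13 and 0.92 ± 0.13, and Hmmr, a spindle protein, by 0.91 ± 0.10. Of 22 cholesterol synthesis genes, 9 fell and 0 rose (14 and 0 adjusted over the list alone). For the cholesterol list camera gave adjusted p = 1.6e-06, and adjusted p = 0.421 with an estimated correlation. Srebf2, the regulator of the pathway, fell by 0.63 ± 0.08, and Mvk, mevalonate kinase, by 0.46 ± 0.08. Fatty acid synthesis and barrier lipids had 5 of 25 genes lower and 0 higher (the same adjusted over the list alone). For the fatty acid synthesis list camera gave adjusted p = 0.00921, and adjusted p = 0.576 with an estimated correlation. Srebf1, the lipogenic regulator, fell by 0.59 ± 0.11. The fatty acid synthesis list was not called without HFD replicate 3 (adjusted p = 0.108) or with fry (0.108).

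Fatty acid oxidation and PPAR targets had 9 of 24 genes higher and 0 lower (the same adjusted over the list alone). For the fatty acid oxidation list camera gave adjusted p = 3.1e-04, and adjusted p = 0.109 with an estimated correlation. Cpt1a, which admits fatty acids to mitochondria, rose by 0.54 ± 0.10, and the mitochondrial carrier Ucp2 by 0.63 ± 0.09. Decr1 and Eci2, enzymes for unsaturated fatty acids, rose by 0.62 ± 0.10 and 0.50 ± 0.09. Glycolysis and hypoxia genes had 9 of 31 genes higher and 0 lower (15 and 0 adjusted over the list alone). For the glycolysis and hypoxia list camera gave adjusted p = 3.1e-04, and adjusted p = 0.397 with an estimated correlation. Bnip3, a mitophagy receptor, rose by 0.71 ± 0.11, and Egln3, an oxygen sensor of the HIF pathway, by 0.57 ± 0.10. Oxidative phosphorylation had 4 of 76 genes higher and 2 lower (0 and 0 adjusted over the list alone), with a median of 0.11. Among all 10367 genes tested, 856 were higher and 908 lower, so these counts alone do not show a rise. For the oxidative phosphorylation list camera gave adjusted p = 0.00700, and adjusted p = 0.720 with an estimated correlation. Its call ended without control replicate 2 (adjusted p = 0.0577), with quantile normalization (0.271) and with fry (0.183). The sweat gland list had 3 of 5 genes higher and 0 lower (4 and 0 adjusted over the list alone). For the sweat gland list camera gave adjusted p = 0.00745, and adjusted p = 0.347 with an estimated correlation. Without a filter on low values it was not called (adjusted p = 0.368, median -0.02). Its risen members were Ehf, Slc12a2, a sodium and chloride cotransporter (0.45 ± 0.07), and Acta2, the smooth muscle actin of myoepithelial cells (1.11 ± 0.20). The luminal keratins Krt8, Krt18 and Krt19 were each below 1 FPKM in every library.

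The other 18 lists were not called in HFD against control (camera adjusted p from 0.132 to 0.966), but single members changed. Krt6a, a keratin of activated and plantar epidermis, rose from 119 ± 19.1 to 250.4 ± 75.8 FPKM (adjusted p = 0.00627). It was the only one called of 7 plantar and stress keratins (2 adjusted over the list alone). Epidermal inflammation and alarmins had 5 of 20 genes higher and 0 lower (the same adjusted over the list alone), including Il1rn, the interleukin 1 receptor antagonist (0.73 ± 0.13). The senescence list had 4 of 15 genes higher and 1 lower (6 and 1 adjusted over the list alone). In it Cdkn2a, the locus of the cell cycle inhibitor p16, went from 0.0799 ± 0.116 to 1.56 ± 0.359 FPKM (adjusted p = 0.00135). FPKM was given per gene, so the transcripts of this locus were not told apart. Clock genes had 6 of 20 genes higher and 4 lower (the same adjusted over the list alone). Tef, a clock output factor related to Dbp, and the repressor Bhlhe41 rose by 1.23 ± 0.13 and 0.91 ± 0.11 beside the fall of Npas2. Differentiation genes had 2 of 39 genes higher and 3 lower (the same adjusted over the list alone). The suprabasal keratins Krt1 and Krt10 and the envelope protein Ivl had 0.30 ± 0.13, 0.20 ± 0.17 and -0.32 ± 0.25, none of them called. Piezo1, a mechanically gated channel, had -0.50 ± 0.12 (adjusted p = 0.0172). That call ended without control replicate 2 or HFD replicate 1 (adjusted p up to 0.0693), with no filter on low values (0.0510) and after a GC correction, alone (0.0810) or with the replicate block (0.0774).

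Hemidesmosome and basement membrane genes had 3 of 24 genes higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.601). Dst, the plakin that anchors keratins at hemidesmosomes, rose by 0.53 ± 0.08, whereas Col4a5, a chain of collagen IV, fell by 0.55 ± 0.09. Itga6 had 0.29 ± 0.07 (adjusted p = 0.0168), a call that ended without control replicate 2 or HFD replicate 2 or 3 (adjusted p up to 0.0648). Basal keratinocyte identity had 1 of 19 genes higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.541). YAP and mechanical response genes had 2 of 22 genes higher and 5 lower (the same adjusted over the list alone, camera adjusted p = 0.966), with a median of 0.05 and a mean of -0.04. Of these, Actn1, an actin crosslinker, rose by 0.48 ± 0.08, whereas Zyx, a focal adhesion protein, fell by 0.71 ± 0.13. Calcium and NFAT signalling had 6 of 20 genes higher and 1 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.132). Calm2, a calmodulin gene, rose by 0.47 ± 0.07. Immediate early genes had 3 of 26 genes higher and 4 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.281). Heat shock and unfolded protein response genes had 2 of 25 genes higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.192). NRF2 genes had 3 of 25 genes higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.370), with a median of -0.01 and a mean of 0.07. Ribosomal protein genes had 0 of 78 genes higher and 1 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.132). Hair follicle and sebaceous markers had 1 of 12 genes higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.966), with a median of -0.04 although the test pointed upward. Type I interferon genes had 0 of 12 genes higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.281) by limma. Of all 10367 genes tested, 1764 were called and 3525 had an unadjusted p under 0.05.

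Fold changes in HFD against control moved with the GC content of the transcripts. Their median was 0.15 in the lowest of 8 GC bins and -0.21 in the highest. Spearman's rho over genes, which are not independent replicates, was -0.46. After a GC correction per library, 606 genes were higher and 555 lower, and 939 were called in the same direction with and without it. The 7 lists called here were also called after the correction (highest camera adjusted p = 0.00119, and 0 of them with an estimated correlation, lowest adjusted p = 0.0995). Ribosomal protein genes were called only after the correction (camera adjusted p = 0.00626, and adjusted p = 0.758 with an estimated correlation, median 0.10). The correction gave 5 genes higher and 2 lower for YAP response genes and 3 genes higher and 2 lower for hemidesmosome and basement membrane genes, against 2 genes higher and 5 lower and 3 genes higher and 4 lower before. Immediate early genes had 1 higher and 1 lower after it, against 3 and 4 before. Basal identity genes had 1 higher and 1 lower, against 1 and 3, and their median went from -0.07 to 0.05. Scaling each library to its total FPKM moved the split to 598 higher and 1165 lower. Without control replicate 2 the counts were 385 higher and 364 lower. They were 449 and 427, 431 and 471, and 485 and 529 without HFD replicates 1, 2 and 3, and the lower count was 599 without control replicate 3.

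**Figure D2:**
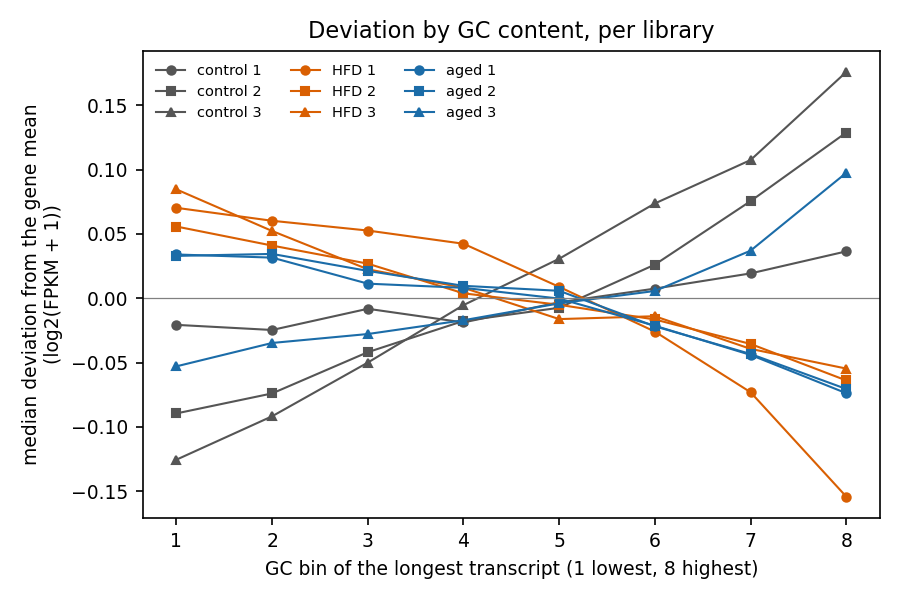
Median deviation of log2(FPKM + 1) from each gene's mean over the 9 libraries (vertical axis) in 8 bins of transcript GC content (horizontal axis), with 1 line per library coloured by group. The lowest minus the highest bin is -0.06, -0.22 and -0.30 in control, 0.22, 0.12 and 0.14 in HFD, and 0.11, 0.10 and -0.15 in aged replicates 1, 2 and 3.

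The comparison of aged with control addressed how basal cells of 24-month-old animals differ from those of 5-month-old ones. Fbp2 rose again, to 7.12 ± 1.52 FPKM (log2 fold change 2.68 ± 0.17, adjusted p = 2.4e-05). Gpha2, at 1.06 ± 0.427 FPKM in control, rose by 2.67 ± 0.18. Cdkn2a was near the detection floor in control, at 0.0799 ± 0.116 FPKM, and reached 3.41 ± 0.413 in aged (2.03 ± 0.14, adjusted p = 2.4e-05). Fos and Atf3, both immediate early genes, rose. Slc38a4, an amino acid transporter, fell by 1.83 ± 0.20, from 10.9 ± 1.06 to 2.38 ± 0.728 FPKM (adjusted p = 7.3e-04). Limma called 416 genes higher and 388 lower, with 51 and 11 changed by at least 1 on the log2 scale.

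The largest rise was in Eno1b, an intronless copy of the glycolytic gene Eno1, at 0.111 ± 0.0610 FPKM in control, 1.17 ± 1.92 in HFD and 9.84 ± 2.59 in aged (3.26 ± 0.43, adjusted p = 0.00198). Eno1b shares 84.5% of its 50-base stretches with other transcripts. The sum of Eno1 and Eno1b was 54.2 ± 4.78 FPKM in control, 65.6 ± 4.31 in HFD and 53.3 ± 2.24 in aged. Depp1, a target of FOXO transcription factors, rose by 2.47 ± 0.38, and Arc, an immediate early gene best known from neurons, by 2.12 ± 0.34. Btg2, an antiproliferative gene, rose by 2.04 ± 0.27. Pcbd1, which recycles the cofactor tetrahydrobiopterin, went from 5.59 ± 0.660 to 25.2 ± 0.779 FPKM (adjusted p = 2.4e-05). Npas2 fell by 1.57 ± 0.20, Adh1 by 1.41 ± 0.19 and Mmp3 by 1.26 ± 0.24. Gpc3, a cell surface proteoglycan, fell by 1.34 ± 0.20, and Has3, a hyaluronan synthase, by 1.27 ± 0.21. Akr1e1, an aldo-keto reductase, and Ttc9, a tetratricopeptide repeat protein, had -1.25 ± 0.27 and -1.07 ± 0.22. Lce1a1 and Lce1b had -1.32 ± 0.30 and -1.02 ± 0.28.

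The calls of these last 4 genes ended when single libraries were left out. The adjusted p reached 0.0724 for Akr1e1 (without control replicate 1 or 3), 0.0562 for Ttc9 (control replicate 2 or 3) and 0.0857 for Lce1a1 (control replicate 1 or 2 or aged replicate 1 or 2). For Lce1b it reached 0.114 (control replicate 2 or 3, HFD replicate 1 or 2, or aged replicate 1 or 3). Without a filter on low values it was 0.0756, 0.0603, 0.0800 and 0.111. A pseudocount of 0.1 also ended the calls of Lce1a1 (0.0543) and Lce1b (0.0867). That of Lce1b further ended with only the 6 libraries compared (0.0641), with library weights (0.0709) and after a GC correction (0.0842). In the M21 annotation of GRCm38, Fbp2 (ENSMUSG00000021456, chromosome 13, 62836877 to 62858422) and Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) are protein-coding genes. So are Eno1b (ENSMUSG00000059040, chromosome 18, 48045335 to 48048412) and Slc38a4 (ENSMUSG00000022464, chromosome 15, 96994820 to 97055956).

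Of 26 immediate early and dissociation response genes, 13 rose and 0 fell in aged (16 and 0 adjusted over the list alone), with a median of 0.57. For the immediate early list camera gave adjusted p = 7.0e-11, and adjusted p = 0.267 with an estimated correlation. Fos, a subunit of AP-1, went from 146 ± 25.5 to 465 ± 50.9 FPKM (adjusted p = 8.8e-04). Atf3, a stress-induced transcription factor, went from 32.2 ± 9.81 to 179 ± 18.6 FPKM (adjusted p = 4.0e-04). Egr1, another immediate early transcription factor, and Zfp36, which destabilises cytokine mRNAs, rose by 1.23 ± 0.14 and 1.46 ± 0.16. Circadian clock genes had 9 of 20 genes higher and 2 lower (11 and 4 adjusted over the list alone). For the clock list camera gave adjusted p = 3.4e-04, and adjusted p = 0.296 with an estimated correlation. Tef and the repressors Bhlhe40 and Bhlhe41 rose by 1.34 ± 0.13, 0.86 ± 0.10 and 1.20 ± 0.11.

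Of 42 cell cycle genes, 8 fell and 0 rose in aged (11 and 0 adjusted over the list alone). For the cell cycle list camera gave adjusted p = 7.0e-07, and adjusted p = 0.445 with an estimated correlation. With fry it was not called (adjusted p = 0.102). Pcna, the replication clamp, fell by 0.44 ± 0.09, and Rrm2, a subunit of ribonucleotide reductase, by 0.35 ± 0.07. Mcm5 and Mcm7 of the replicative helicase had -0.52 ± 0.12 and -0.41 ± 0.09. Mki67 was at 88.4 ± 11.7 FPKM against 89.5 ± 10.1 in control (adjusted p = 0.921). Without control replicate 3 the adjusted p reached 0.0543 for Pcna, and without control replicate 3 or aged replicate 1 it reached 0.0686 for Rrm2. Without control replicate 3 or aged replicate 1 or 2 it reached 0.0883 for Mcm7, and 0.104 for Mcm5, whose call also ended without control replicate 2. Without a filter on low values it was 0.0789 for Mcm5 and 0.0554 for Mcm7, and with only the 6 libraries compared 0.0570 for Mcm7.

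Of 24 hemidesmosome and basement membrane genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone). For the hemidesmosome list camera gave adjusted p = 7.2e-05, and adjusted p = 0.376 with an estimated correlation. Col4a5 fell by 0.64 ± 0.09 (adjusted p = 0.00198). Ribosomal protein genes had 2 of 78 genes higher and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.15. Among all 10367 genes tested, 416 were higher and 388 lower, so the 2 calls alone do not show a rise. For the ribosomal list camera gave adjusted p = 1.8e-06, and adjusted p = 0.486 with an estimated correlation. With fry it was not called (adjusted p = 0.189). Fatty acid oxidation had 1 of 24 genes higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.24. For the fatty acid oxidation list camera gave adjusted p = 7.2e-05, and adjusted p = 0.0847 with an estimated correlation. Inflammation and alarmins had 4 of 20 genes higher and 0 lower (5 and 0 adjusted over the list alone). For the inflammation list camera gave adjusted p = 0.00455, and adjusted p = 0.267 with an estimated correlation. Tnfaip3, an inhibitor of NF-kB signalling, rose by 1.05 ± 0.15, and Il1rn by 0.81 ± 0.13. Type I interferon genes had 3 of 12 genes higher and 0 lower (the same adjusted over the list alone). For the interferon list camera gave adjusted p = 0.00285, and adjusted p = 0.161 with an estimated correlation. Ifi27l2a, an interferon-induced gene, and Psmb8, a subunit of the immunoproteasome, rose by 1.10 ± 0.14 and 0.82 ± 0.15. With no filter on low values the interferon list was not called (adjusted p = 0.116).

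NRF2 genes had 5 of 25 genes higher and 0 lower (7 and 1 adjusted over the list alone). For the NRF2 list camera gave adjusted p = 0.00287, and adjusted p = 0.332 with an estimated correlation. Gsta3, a glutathione transferase, rose by 1.02 ± 0.13, and Cat, catalase, by 0.54 ± 0.07. Hair follicle and sebaceous markers had 2 of 12 genes higher and 0 lower (4 and 1 adjusted over the list alone). For the hair follicle list camera gave adjusted p = 0.00285, and adjusted p = 0.296 with an estimated correlation. Krt28, an inner root sheath keratin, went from 0.364 ± 0.155 to 2.65 ± 0.382 FPKM (adjusted p = 4.0e-04). Mgst1, a microsomal glutathione transferase, went from 27.2 ± 5.59 to 42.0 ± 0.891 FPKM (adjusted p = 0.00912). The senescence list had 3 of 15 genes higher and 1 lower (6 and 2 adjusted over the list alone). For the senescence list camera gave adjusted p = 0.0344, and adjusted p = 0.267 with an estimated correlation. Cdkn2b, the neighbour of Cdkn2a that encodes the inhibitor p15, rose by 1.10 ± 0.17, and Igfbp4, an IGF binding protein, by 0.70 ± 0.11. The senescence call ended without control replicate 1 or 2 or aged replicate 3 (adjusted p up to 0.0827) and with the replicate numbers as a block (0.0567). With no filter on low values its adjusted p was 0.640 (median -0.07). With a minimum mean of 5 FPKM its direction turned (median -0.12, adjusted p = 0.793).

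Glycolysis and hypoxia genes had 6 of 31 genes higher and 1 lower (7 and 1 adjusted over the list alone). For the glycolysis and hypoxia list camera gave adjusted p = 0.0134, and adjusted p = 0.357 with an estimated correlation. Slc16a3, a lactate exporter, rose by 0.85 ± 0.13. Without control replicate 2 this list was not called (adjusted p = 0.0716). Of 22 cholesterol synthesis genes, 2 fell and 0 rose (the same adjusted over the list alone). For the cholesterol list camera gave adjusted p = 0.0167, and adjusted p = 0.486 with an estimated correlation. Its call ended without control replicate 1 or aged replicate 1 or 3 (adjusted p up to 0.187) and with fry (0.229). Spinous and granular differentiation had 5 of 39 genes higher and 2 lower (7 and 4 adjusted over the list alone). For the differentiation list camera gave adjusted p = 0.0406, and adjusted p = 0.722 with an estimated correlation. Krt1, a suprabasal keratin, went from 1259.6 to 1936 FPKM on average (0.61 ± 0.13, adjusted p = 0.0198). Mt4, a metallothionein of stratified epithelium, rose by 0.75 ± 0.11. Krt10, the partner of Krt1, had 0.53 ± 0.17 and did not pass (adjusted p = 0.0761). The differentiation call ended without control replicate 3, HFD replicate 1 or aged replicate 1 or 2 (adjusted p up to 0.750). It also ended with no filter on low values (0.221), with quantile normalization (0.126) and with fry (0.588). The Krt1 call ended without control replicate 1 or 3 or aged replicate 1 or 2 (up to 0.0729) and with no filter (0.0877).

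The other 11 lists were not called in aged against control (camera adjusted p from 0.0778 to 0.884). Thbs1, the matrix glycoprotein thrombospondin 1, rose from 13.1 ± 2.54 to 33.5 ± 3.45 FPKM (adjusted p = 4.0e-04). Axl, a receptor tyrosine kinase, rose by 0.78 ± 0.08, and Ccn1, a target of YAP, by 1.26 ± 0.20. Basal keratinocyte identity had 1 of 19 genes higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.0844). YAP and mechanical response had 3 of 22 genes higher and 4 lower (5 and 8 adjusted over the list alone, camera adjusted p = 0.385). Heat shock and unfolded protein response had 4 of 25 genes higher and 2 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.679). Oxidative phosphorylation had 1 of 76 genes higher and 1 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0778). Fatty acid synthesis and barrier lipids had 0 of 25 genes higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.554), with a median of -0.01 and a mean of 0.05. Plantar and stress keratins and calcium signalling had 0 of 7 and 0 of 20 genes called by limma, also adjusted over the list alone. Of all 10367 genes tested, 804 were called and 2674 had an unadjusted p under 0.05. Piezo1 had -0.52 ± 0.12 (adjusted p = 0.0232). That call ended without control replicate 2 or aged replicate 1 (adjusted p up to 0.0885) and with no filter on low values (0.0634).

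**Figure D3:**
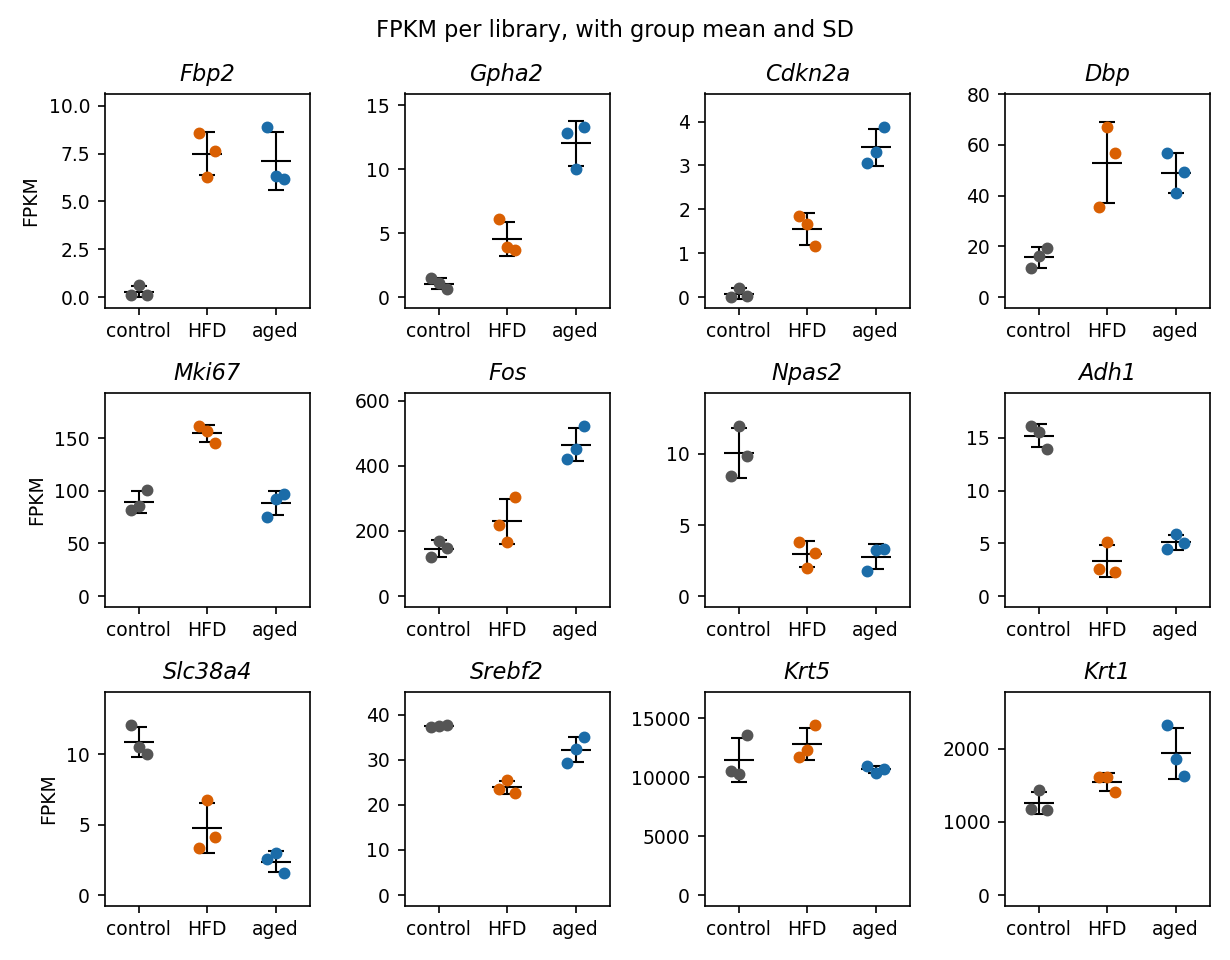
FPKM of 12 genes in control, HFD and aged, 1 point per library, with the group mean as a horizontal line and the SD as a vertical bar (n = 3). Fbp2 and Cdkn2a stand apart from control in both groups, whereas Mki67 is high in HFD, at 155 ± 7.89 FPKM, and Fos in aged, at 465 ± 50.9.

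Fold changes in aged against control also declined with GC content (Spearman's rho -0.33 over genes). The GC correction gave 416 genes higher and 358 lower, and 648 were called in the same direction with and without it. Oxidative phosphorylation genes were called only after the correction (camera adjusted p = 0.0282, and adjusted p = 0.702 with an estimated correlation, median 0.06). Heat shock genes had 2 genes higher and 4 lower called after it, against 4 genes higher and 2 lower before. Total scaling moved the split to 358 higher and 507 lower. The counts were 193 higher and 130 lower without control replicate 2 and 200 and 119 without control replicate 3. They were 187 and 113 without aged replicate 1 and 231 and 157 without aged replicate 2. Without aged replicate 3, the aged library nearest to control on the first component, they were 586 and 661. Without HFD replicate 2 the lower count was 255, and with only the 6 libraries compared the counts were 269 and 192.

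The comparison of aged with HFD showed where the groups parted. Of 42 cell cycle genes, 32 were lower in aged and 0 higher (37 and 0 adjusted over the list alone), with a median of -0.57. For the cell cycle list camera gave adjusted p = 5.7e-26, and adjusted p = 0.403 with an estimated correlation. Of 26 immediate early genes, 17 were higher in aged and 0 lower (21 and 0 adjusted over the list alone), with a median of 1.01. For the immediate early list camera gave adjusted p = 2.0e-17, and adjusted p = 0.403 with an estimated correlation. Mki67 was at 88.4 ± 11.7 FPKM in aged and 155 ± 7.89 in HFD (adjusted p = 0.00217). Kif11, a spindle motor, Ccna2, cyclin A2, and Bub1, a checkpoint kinase, had log2 differences of -0.75 ± 0.09, -0.77 ± 0.09 and -0.78 ± 0.09. Egr1 and the AP-1 subunits Fosb and Junb were higher by 1.35 ± 0.14, 1.51 ± 0.19 and 1.12 ± 0.15. Limma called 367 genes higher and 461 lower in aged, with 32 and 12 at a log2 difference of at least 1.

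The largest excesses in aged were Eno1b (2.64 ± 0.43, adjusted p = 0.00501), Depp1 (2.48 ± 0.38), Arc (2.17 ± 0.34), Pcbd1 (1.66 ± 0.12) and Btg2 (1.64 ± 0.27). Those in HFD were S100a8 (-1.75 ± 0.40), Ehf (-1.58 ± 0.23), Acta2 (-1.50 ± 0.20), Tnc, the matrix protein tenascin C (-1.48 ± 0.17), and Krt6a (-1.40 ± 0.19). The S100a8 call ended without HFD replicate 2 or 3 or aged replicate 3 (adjusted p up to 0.0754) and with no filter on low values (0.0890). It also ended with only the 6 libraries compared (0.0510) and with limma's robust setting (0.0709). Cdkn2a was higher in aged by 0.79 ± 0.14 (adjusted p = 0.00689), a call lost with a pseudocount of 0.1 (adjusted p = 0.107). Cholesterol synthesis had 3 of 22 genes higher and 0 lower (the same adjusted over the list alone). For the cholesterol list camera gave adjusted p = 4.4e-04, and adjusted p = 0.496 with an estimated correlation. Fatty acid synthesis and barrier lipids had 6 of 25 genes higher and 0 lower (7 and 0 adjusted over the list alone). For the fatty acid synthesis list camera gave adjusted p = 6.7e-04, and adjusted p = 0.487 with an estimated correlation. Srebf2 was higher in aged by 0.42 ± 0.08 and Srebf1 by 0.58 ± 0.11. Me1, the malic enzyme that supplies NADPH, was higher by 0.69 ± 0.10. Hair follicle and sebaceous markers had 4 of 12 genes higher and 0 lower (the same adjusted over the list alone). For the hair follicle list camera gave adjusted p = 0.00564, and adjusted p = 0.487 with an estimated correlation. Mgst1 was higher in aged by 0.75 ± 0.11, and Cidea, a lipid droplet protein, by 1.50 ± 0.27. With a minimum mean of 5 FPKM that list was not called (adjusted p = 0.0849). By fry it was not called either (adjusted p = 0.0641), nor were the fatty acid synthesis (0.0641) and cholesterol (0.107) lists.

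Hemidesmosome and basement membrane genes had 0 of 24 genes higher and 3 lower (the same adjusted over the list alone). For the hemidesmosome list camera gave adjusted p = 0.00112, and adjusted p = 0.568 with an estimated correlation. Itga6 was at -0.40 ± 0.07 in aged against HFD, and Vcl, the adhesion protein vinculin, at -0.50 ± 0.07. Differentiation genes had 3 of 39 genes higher and 1 lower (the same adjusted over the list alone). For the differentiation list camera gave adjusted p = 0.00622, and adjusted p = 0.623 with an estimated correlation. Ribosomal protein genes had 0 of 78 genes higher and 0 lower (the same adjusted over the list alone) by limma, with a median of 0.06. Of all 10367 genes tested, 828 were called and 2531 had an unadjusted p under 0.05. For the ribosomal list camera gave adjusted p = 0.00622, and adjusted p = 0.636 with an estimated correlation. Clock genes had 1 of 20 genes higher and 0 lower (the same adjusted over the list alone). For the clock list camera gave adjusted p = 0.00994, and adjusted p = 0.523 with an estimated correlation. Each of these 4 calls ended without a single library. The adjusted p reached 0.0528 for hemidesmosomes and 0.483 for differentiation, both without HFD replicate 3. It reached 0.284 for ribosomal proteins (HFD replicate 3 or aged replicate 1 or 2) and 0.150 for the clock (HFD replicate 1 or aged replicate 3). Library weights also ended the calls of differentiation and the clock (0.0577 for both), and a minimum mean of 5 FPKM that of the clock (0.0900). All 4 ended with fry (adjusted p = 0.129 for hemidesmosomes and the clock, 0.456 for differentiation and ribosomal proteins). The other 16 lists were not called (camera adjusted p from 0.0667 to 0.718). Among them, plantar and stress keratins had a median of 0.07 but a mean of -0.35. Inflammation had a median of 0.08 and a mean of -0.02, and YAP response a median of -0.04 and a mean of 0.04. The gene counts were 208 higher and 267 lower without HFD replicate 1, 182 and 197 without HFD replicate 2 and 168 and 222 without HFD replicate 3. They were 196 and 249 without aged replicate 1, and 338 and 509 after the GC correction.

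**Figure D4:**
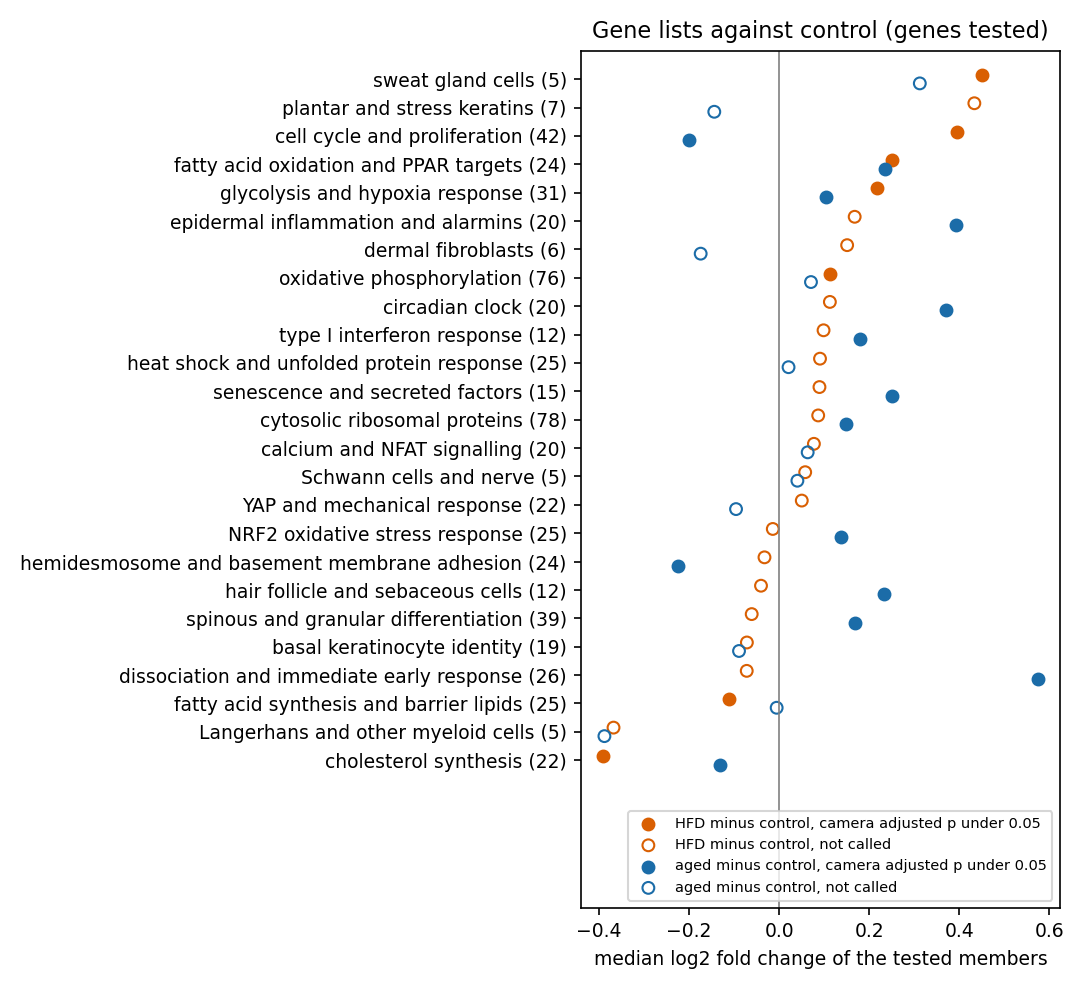
Median log2 fold change against control (horizontal axis) of the tested members of 25 gene lists, with HFD in orange and aged in blue, filled where the camera adjusted p with the preset correlation was under 0.05, and the number of genes tested in brackets. The cell cycle list lies at 0.40 in HFD and -0.20 in aged, and the immediate early list at -0.07 and 0.57.

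Some genes were called in the same direction in HFD and in aged, both against the same 3 controls. Fbp2, Dbp, Vsnl1 and Gpha2 rose in both groups, with Dbp at 15.6 ± 4.06 FPKM in control, 53.0 ± 15.9 in HFD and 49.0 ± 7.85 in aged. Adh1, Npas2, Mmp3 and Slc38a4 fell in both, with Npas2 at 10.1 ± 1.75, 2.95 ± 0.894 and 2.78 ± 0.859 FPKM. Slc38a4 fell by 1.09 ± 0.20 in HFD. Lce1a1 was also called lower and Igfl3 higher in both. The Igfl3 call in aged (1.28 ± 0.35) ended without any library except HFD replicate 2 or aged replicate 3 (adjusted p up to 0.171). It also ended after the GC correction (0.0567), with no filter (0.130), quantile normalization (0.0623), the robust setting (0.0966) and the 6 libraries compared (0.0641). In all, 180 genes were higher and 201 lower in both, 381 in the same direction. Independent lists would share 34.3 higher and 34.0 lower, a value that leaves out the shared controls. Simulated data in which no group differed shared 0, which is expected where almost no genes are called and is no measure of overlap. The fold changes correlated at r = 0.56 over genes, which are not independent replicates, against 0.50 in the simulation. Their covariance was 0.0370, against 0.00672. After the GC correction 263 genes were shared, r was 0.53 against 0.50 in the corrected simulation, and the covariance was 0.0305 against 0.00663. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. The GC trend (lowest minus highest bin) was negative in all 3 control libraries and in aged replicate 3 and positive in the other 5, and the labels give no batch of library preparation. The shared count was 132 without control replicate 2, 169 without control replicate 3 and 616 without aged replicate 3. It was 214, 212 and 239 without HFD replicates 1, 2 and 3, and 172 and 194 without aged replicates 1 and 2.

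Markers of other cell types that the gate could hold ranged from 0 to high levels. The highest member had a mean of 97.2 FPKM among dermal fibroblast markers, 49.0 among those of adipocytes, 37.7 among those of T cells (Thy1) and 26.2 among those of Schwann cells. It was 17.6 in endothelial and mural cells and 8.68 in Langerhans and myeloid cells. For sweat gland cells it was 85.0, for hair follicle and sebaceous cells 60.7, for skeletal muscle 5.00, for melanocytes 3.02, for Merkel cells 0.819 and for erythroid cells 0.125. Only 2 of 22 T cell markers and 1 of 13 adipocyte markers reached the expression minimum. The endothelial and mural list also held Notch3, of the differentiation list, and Acta2, of the sweat gland list. A high member of a list therefore need not come from that cell type. The fibroblast collagens Col1a1, Col1a2 and Col3a1, the melanocyte genes Dct and Tyrp1, the leukocyte gene Ptprc and the endothelial gene Pecam1 had group means of at most 0.138 FPKM. The adipocyte gene Adipoq, the muscle gene Ckm and the haemoglobin gene Hbb-bs reached at most 0.304, and the Merkel cell keratin Krt20 was listed at 0. These genes were singled out from their lists after their values were seen. Dcn, a fibroblast proteoglycan, was at 5.22 ± 1.09 FPKM in control and 2.03 ± 0.531 in HFD (adjusted p = 0.00239). Postn, a member of the same list, went the other way and was called higher in HFD, as given above. Thy1, expressed by fibroblasts, T cells and some keratinocytes, fell from 49.8 ± 3.71 to 34.6 ± 2.70 FPKM in HFD and 28.6 ± 4.06 in aged. Mfge8, a secreted protein of Langerhans cells and others, fell by 0.74 ± 0.11 in aged. Dermal fibroblast markers had 1 of 6 genes higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.902) in HFD and 0 of 6 genes higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.255) in aged. Langerhans and myeloid markers had 0 of 5 genes higher and 1 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.171) in HFD and 0 of 5 genes higher and 1 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.0795) in aged. Schwann cell and nerve markers had 1 of 5 genes higher and 0 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.653) in HFD. In aged they had 0 of 5 genes higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.884), with a median of 0.04 although the test pointed down. Markers with fewer than 5 members at the expression minimum were not tested. These were MHC class II (3), melanocytes (1), Merkel cells (0), T cells (2), endothelial and mural cells (3), skeletal muscle (3), adipocytes (1) and erythroid cells (0). Cd74, the MHC class II invariant chain, was at 5.25 ± 2.73, 3.54 ± 1.91 and 3.80 ± 0.947 FPKM, with no call. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 9 libraries, and none differed between groups (lowest adjusted p = 0.0821).

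Several named genes are uncertain because their sequence occurs elsewhere. Of their 50-base stretches, 45.5% in Krt6a, 72.2% in Eno1, 31.8% in Pcna, 26.0% in Mcm7, 26.5% in Me1 and 21.9% in Bnip3 are shared with transcripts of other genes. The share is 19.9% in Lce1a1, 24.4% in Lce1b, 14.4% in Krt14 and 12.7% in Calm2. Gpha2 overlaps Ppp2r5b on the opposite strand. Ppp2r5b was at 8.78 ± 0.400 FPKM in control, 8.59 ± 0.808 in HFD and 8.08 ± 1.41 in aged. Actn1, Adh1, Bhlhe40, Bhlhe41, Bnip3, Ccna2, Dbp, Dst, Eci2, Has3, Junb, Krt10, Krt5, Krt6a, Ly6k, Mcm7, Me1, Piezo1, Psmb8, Slc16a6, Srebf1, Tef, Thbs1, Tnc, Ucp2, Vcl, Zfp36 and Zyx also overlap other genes on the opposite strand, which were not examined singly.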

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

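The tests chosen only after the result was seen were heat shock against immediate early genes, the time of day for clock genes and total scaling. So was the GC correction, alone, with the replicate block or without aged replicate 3. The heat shock test was read more strictly after its result. A test of a growth network, given below, was prompted by falls already seen. For 6 genes and 1 list the effects of HFD and of age against control were both called and opposite, beside 381 genes called in the same direction. The difference between HFD and aged is given from the comparison of aged with HFD. Cdca3, a mitotic regulator, had log2 fold changes of 0.38 in HFD and -0.33 in aged against control, -0.71 between them (adjusted p = 0.00200 for the difference). Cenpa, the centromeric histone, had 0.35 in HFD and -0.38 in aged against control, -0.73 between them. Depdc1a, a mitotic gene of which 62.6% of 50-base stretches are shared with other transcripts, had 0.69 in HFD and -0.49 in aged against control, -1.18 between them. Baiap2l1, an adaptor of the actin cytoskeleton that overlaps other genes on the opposite strand, had -0.66 in HFD and 0.77 in aged against control, 1.42 between them. S100a1, a calcium-binding protein, had 0.27 in HFD and -0.36 in aged against control, -0.63 between them. Eno1, the glycolytic enolase, which shares 70.5% of its 50-base stretches with Eno1b, had 0.25 in HFD and -0.30 in aged against control, -0.56 between them. Eno1 and Eno1b together were at 54.2 FPKM in control, 65.6 in HFD and 53.3 in aged, so the fall of Eno1 in aged is not a fall of the sum. Without any 1 library the difference between HFD and aged stayed called for all 6. That difference joins both called effects. Its call therefore largely follows from how the genes and the list were picked, and is no separate support. Without aged replicate 1 or 2, all but Baiap2l1 lost the call in aged against control, and without control replicate 2 or HFD replicate 1, Cdca3, Cenpa, S100a1 and Eno1 lost that in HFD (adjusted p up to 0.169). Each library except aged replicate 3 ended at least 1 of these calls when left out. With only the 6 libraries compared, those 5 lost the call in aged (adjusted p up to 0.0903), and S100a1 that in HFD (0.0527). No filter on low values ended the calls of Cdca3, Cenpa, Depdc1a and S100a1 in aged (up to 0.107) and of Cenpa, S100a1 and Eno1 in HFD (up to 0.0779), total scaling those of the same 3 in HFD (up to 0.108), and quantile normalization those of S100a1 and Eno1 in HFD (0.0621 and 0.0572). The GC correction ended those of Cenpa in HFD (0.0586) and Eno1 in aged (0.0672, 0.0794 with the replicate block). S100a1 was also not called with the replicate block in HFD (0.0517) or with it and the GC correction in aged (0.0514), nor Cdca3 with library weights in aged (0.0527). The cell cycle list had medians of 0.40 in HFD and -0.20 in aged against control, and -0.57 between them. It was called in none of the 3 with an estimated correlation (adjusted p = 0.576, 0.445 and 0.403). With fry the adjusted p was 0.0495, 0.102 and 0.0184, so the fall in aged was not called. Its 24 mitotic members had uncorrected medians of 0.60 in HFD and -0.16 in aged, and its 18 S phase members 0.01 and -0.29. The rise in HFD thus lay in the mitotic members, whereas the fall in aged was larger in the S phase members.

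The rise of cell cycle genes in HFD kept 0.884 of its median after the GC correction, which argues against GC content as the whole cause. The S phase members had a GC-corrected median of 0.02 over 18 genes and the mitotic members 0.54 over 24 (permutation p = 2.0e-05, two-sided), a ratio of 0.0297. The permutation shuffles genes, which are not independent replicates, so its p does not measure the spread between libraries. In these libraries the rise lay in the mitotic members and not in the S phase members. The ratio lay below the bound set before the result for a larger share of cells in every phase of the cycle, which goes against that explanation. The test does not exclude it, since no spread between libraries was taken for the ratio. A longer passage through mitosis, or a different mixture of cycling cells at the gate, may also account for the rise and was not tested. Effects of diet stay open as a hypothesis.

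The rise of immediate early genes in aged had 1.13 times its median after the GC correction, which argues against GC content. Inducible heat shock genes had a median of 0.11 over 12 genes (-0.40 to 0.72), against 0.57 for the immediate early list, a ratio of 0.200 (permutation p = 0.0363, two-sided). Hspb1 (0.72 ± 0.13, with 51.6% of its stretches shared) and Dnajb1 (0.44 ± 0.08) were themselves called higher, so the members go both ways and the test decides nothing. Dissociation stress that raises both sets, or other handling that raises immediate early genes alone, may account for the rise and cannot be told apart from age, which stays open as untested.

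The shift of clock genes in HFD and aged kept at least 0.979 of its size after the GC correction and 0.879 without any 1 control library, which argues against GC content and against a single control library out of phase. Clock outputs and repressors (10) had medians of 0.67 in HFD and 0.97 in aged, and 5 genes of the opposite phase, activators with the repressors that follow them, -0.91 and -0.60. The differences were 1.58 and 1.56. Control libraries collected at another time of day cannot be told apart from an effect of diet and age on the clock, because the labels give no collection times. Either may account for the shift.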

How the results depend on the processing

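The GC correction, alone, with the replicate block or without aged replicate 3, and total scaling were chosen only after the data were seen. Counts depended most on a minimum log2 fold change of 1, which left 19 genes higher and 20 lower in HFD, 51 and 11 in aged against control, 32 and 12 in aged against HFD, and 16 shared, because it asks for a larger change. Without a filter on low values, which adds genes to the adjustment, the count was 597 lower in HFD, 244 lower in aged against control, 225 higher in aged against HFD, and 250 shared. With only the 6 libraries compared it was 269 and 192 in aged against control, 947 and 1008 in HFD against control and 333 and 372 in aged against HFD, and the cause was not tested. The GC correction gave 555 lower in HFD, and the cause was not tested beyond the trend it removes. Of the 75 list results, 0 were called with the estimated correlation and 19 with fry, against 30. The senescence list in aged against control reversed with a mean of at least 5 FPKM (-0.12, adjusted p = 0.793), and the cause was not tested.

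Leaving out 1 library gave 385 (without control replicate 2) to 1037 (without aged replicate 3) genes higher and 364 (without control replicate 2) to 1072 (without aged replicate 3) lower in HFD against control. In aged against control it gave 187 (without aged replicate 1) to 586 (without aged replicate 3) higher and 113 (without aged replicate 1) to 661 (without aged replicate 3) lower, and in aged against HFD 168 (without HFD replicate 3) to 355 (without control replicate 2) higher and 197 (without HFD replicate 2) to 435 (without control replicate 3) lower. Genes differing among the groups ranged from 1167 (without HFD replicate 2) to 2474 (without aged replicate 3), and shared genes from 132 (without control replicate 2) to 616 (without aged replicate 3). Of 281 called gene and list results, 106 lost their call without at least 1 library, and of the named genes called, 68 with no filter, 23 with only the 6 libraries compared, 21 after the GC correction (30 without aged replicate 3) and 14 with quantile normalization. Median-ratio scaling moved nothing, since the deposited values were scaled in that way, and tests nothing. Scaling moved the median of all genes by less than 0.1. The self-test, with 200 of 10367 genes changed, found 9.10% of changes of 0.25, so changes of that size were mostly missed there. Many more genes were called in HFD against control, which eases the adjusted threshold, so the share found in the data may differ. Depth sets a floor near 0 FPKM for genes such as Cdkn2a in control.

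The libraries were not treated as paired by replicate number. Deviations of libraries with the same number correlated at -0.05 to 0.27, with 5 of 9 pairs over 0.1. With the replicate block the counts were 978 higher and 1083 lower in HFD, 557 and 580 in aged against control, and 465 and 522 in aged against HFD. With the GC correction and the replicate block together they were 671 and 598 in HFD, 468 and 404 in aged against control, and 401 and 568 in aged against HFD.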

Other observations

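The growth network test below was prompted by the falls of Slc38a4 and Gpc3, both members of its list, and its stricter reading was adopted only after the result was seen. The genes of this paragraph were also chosen after their values were seen. B2m, the light chain of MHC class I, went from 74.0 ± 16.6 FPKM in control to 154 ± 20.9 in HFD and 142 ± 24.1 in aged (adjusted p = 0.00248 and 0.00735). Ccnd1, the cyclin that opens the cell cycle in G1, rose by 0.52 ± 0.08 in HFD and 0.61 ± 0.08 in aged. Col12a1, a fibril-associated collagen, rose by 0.49 ± 0.08 in HFD. Per3, a clock gene of the negative limb, rose by 0.68 ± 0.13 in HFD and 0.86 ± 0.13 in aged. Arntl, the partner of Npas2, fell by 1.02 ± 0.18 in HFD and 0.81 ± 0.18 in aged. The Arntl call in aged ended without control replicate 2 or 3 or aged replicate 1 (adjusted p up to 0.0793) and without a filter on low values (0.0709). Ccnd1 and Arntl overlap other genes on the opposite strand.

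Slc38a4 and Gpc3, which fell in aged, belong to a network of imprinted and coregulated genes that declines with postnatal growth. Of 25 listed members 7 were tested, 0 were called higher and 2 lower. Their median was -0.0197 (camera p = 0.0396, and p = 0.0784 with an estimated correlation), and -0.01 without Slc38a4 and Gpc3. The test cannot tell whether such a network fell, since both called members prompted it.

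A difference in library preparation on the side of the controls may lie behind part of the counts against control and of the genes shared by HFD and aged. The labels give no batch, so this was not tested. The GC correction, chosen after the data were seen, removes only the trend with GC content, and left 606 genes higher and 555 lower in HFD, 416 and 358 in aged, and 263 shared.

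Other splits of the libraries into 2 groups of 3 called at most 0 genes, against 1764 in HFD against control, 804 in aged against control and 828 in aged against HFD. In each comparison only 1 of the 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05. Every other split, here and in the draws below, mixed libraries of different groups. A difference between the groups from any cause then widens the spread and lowers the calls, so low counts in other splits do not tell the cause. Of 100 drawn splits into 3 groups, 1 gave as many genes as the F test's 2110, the real one, and the highest other gave 152. The real grouping was thus the highest of the 100 for these libraries. The samples of a group may not be separate animals, so this does not exclude chance differences between animals or preparations.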
